A study of Mus musculus with 12 samples.

How the data were processed

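ChIP-seq libraries were made from mouse embryonic fibroblasts of passage 9-10 with an antibody to STAT5 or with IgG and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Groups were taken from the sample titles: wild type, Stat5-null, Stat5-null with an empty control, and Stat5-null with STAT5A overexpression. Of the 12 libraries, 3 have a deposited region list used here, namely stimulated wild-type cells and replicates 1 and 2 of stimulated overexpressing cells. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

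The values used are genomic positions (start, end and, in the wild-type list and replicate 1, a summit) of called regions on build mm9, as deposited by the authors. No height, fold enrichment, p-value or read count comes with them, so regions could not be ranked by strength. The region names of replicate 2 begin with MACS, so those regions were called with that program, per the file headers and names. The caller of the other lists, its version, the aligner, the control libraries and the thresholds are not given in the sources used here. The labels attach the list of replicate 2 to an unstimulated and a stimulated STAT5 library of the repeat and to no IgG library, and the other lists to a STAT5 and an IgG library, so the control for replicate 2 may differ. The lists differ in form as well. All 71561 replicate 1 regions and 87.1% of wild-type regions have a deposited start whose last digit is 2 and an end whose last digit is 0 or 1, and 1.95% of replicate 2 regions do. Such regions are called on-grid, that is, on a 10 bp grid with a tolerance of 1 bp at the end. Lists called in different ways differ in number, width and edges of regions for reasons other than binding. Each list is of 1 library, and no region overlapped another within its list.

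Positions were treated as BED intervals. An overlap of at least 1 bp counted as shared. Shares have 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Chance overlap was taken from 1000 random placements that kept each region's width and chromosome, between the first and last region of that chromosome in any list. Gaps in the assembly and sequence that cannot be mapped were not excluded, so this chance level is somewhat low, and regions moved together by 10 to 100 kb gave a second level. Median widths were compared by a two-sided permutation test with 100000 resamples. Densities per Mb used the end of the last region as the length of a chromosome. Ratios of chromosome 10 to the other autosomes were taken over whole 5 Mb windows, with intervals from 1000 bootstrap draws of windows, and they were added after the densities had been seen. The depth of each library is unknown, which leaves open how far the numbers of regions depend on it.

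The interval functions were tested on simulated data: with 10, 30 and 50% of 13278 randomly placed wild-type regions planted on replicate 1 regions, 9.93, 30.2 and 50.1% were recovered after subtraction of chance. The planted regions had the exact positions of replicate 1 regions, so partial overlaps like those in the data were not simulated. Overlap counts matched those of bedtools 2.31.1 in every pair of lists. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

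The tests, the alternatives and the rule for named regions were fixed before the data were examined, apart from those said to be chosen later. The rule was to name members of fixed gene lists (STAT5 and SOCS targets, JAK-STAT components, fibroblast, liver, mammary, lymphoid, neuronal and other genes) with a region nearby, the 10 highest regions of each list and the 5 highest regions common to both overexpression replicates and not in wild type. It needed a score and gene positions on mm9. Neither was at hand, since the gene table used for mouse is of GRCm38 and no coordinates were converted between builds, so none of the gene lists has a result. Regions were ranked by width in place of the score, a choice made after the files were seen. The comparisons of summits, width classes, spacing, 1 Mb windows and parts of the wild-type list were also added then. The planned shares of regions at promoters, near genes and with the STAT recognition sequence were not computed for the same reason. Stimulated and unstimulated cells, and cells with and without STAT5, were not compared, since no list of the unstimulated or Stat5-null cells was analysed here.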

Results

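STAT5 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts, the connective tissue cells grown out of fetuses. STAT5A and STAT5B, encoded by the neighbouring genes Stat5a and Stat5b, are transcription factors that are phosphorylated and enter the nucleus after cytokine or growth hormone signalling. Wild-type cells, cells lacking Stat5, and cells lacking Stat5 in which STAT5A was overexpressed were starved of serum for 5 h and then given growth hormone at 1 µg/ml for 45 min. Overexpressing cells were also sampled without stimulation. The series holds 12 libraries, made with an antibody to STAT5 or with control IgG. Region lists for 3 of them were analysed here: stimulated wild-type cells (1 library) and stimulated overexpressing cells (replicates 1 and 2, the second titled as a repeat of the first). The 3 lists give positions on mouse genome build mm9 without a height, score or p-value for any region, and the sequencing depth of the libraries is unknown. Regions of the other 9 libraries, which include the unstimulated and the Stat5-null cells, were not analysed here. The background in cells without STAT5 therefore has no value beside those given below.

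The first comparison asked how far binding spreads when STAT5A is abundant. The wild-type list held 13278 regions, which together covered 5.21 Mb of the genome. The overexpressing cells had 71561 regions in replicate 1 and 71803 in replicate 2, a mean of 71682 ± 171 (SD, n = 2), or 5.40 times the wild-type number. These regions covered 30.5 ± 0.594 Mb (SD, n = 2). The replicate lists may have been called in different ways and with different controls, so these SDs may not measure the spread between replicates. Coverage was 5.77 and 5.93 times that of wild type in replicates 1 and 2, slightly more than the number of regions. Median widths were 379 bp in wild type, 398 bp in replicate 1 and 378 bp in replicate 2, and mean widths were 393, 421 and 431 bp. With 1 wild-type library the difference between genotypes has no replicate check on that side, and no p-value is given. The wild-type list and replicate 1 share a file format that the repeat does not, and the libraries' depths, which also set how many regions are called, are unknown.

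Replicates of the overexpressing cells were compared next. Of the replicate 1 regions, 37165 (51.9%, 95% exact binomial interval 51.6 to 52.3%) overlapped a replicate 2 region by at least 1 bp, and 30951 replicate 2 regions (43.1%, interval 42.7 to 43.5%) overlapped one of replicate 1. When the overlap had to cover at least 50% of both regions, the shares were 32.7% and 32.6%. Random placement of the second list on its own chromosomes gave 2.47% and 2.45%, and none of 1000 placements reached the observed share in either direction (permutation p = 0.001, one-sided, the smallest these placements can give). Regions found in both replicates were wider. In replicate 1 their median width was 458 bp, against 348 bp for regions not found in replicate 2, and in replicate 2 the medians were 468 bp and 329 bp (p = 1e-05 for each list, two-sided permutation test over regions with 100000 resamples, the smallest they can give). Of the narrowest 20% of replicate 1 regions 32.9% overlapped replicate 2, and of the widest 20% 77.4% did, where random placement gave 1.83% and 3.29%. The corresponding shares for replicate 2 regions were 20.9% and 77.0%. Regions of 1 list are not independent replicates, so these tests and intervals describe the lists and cover counting error only.

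**Figure D1:**
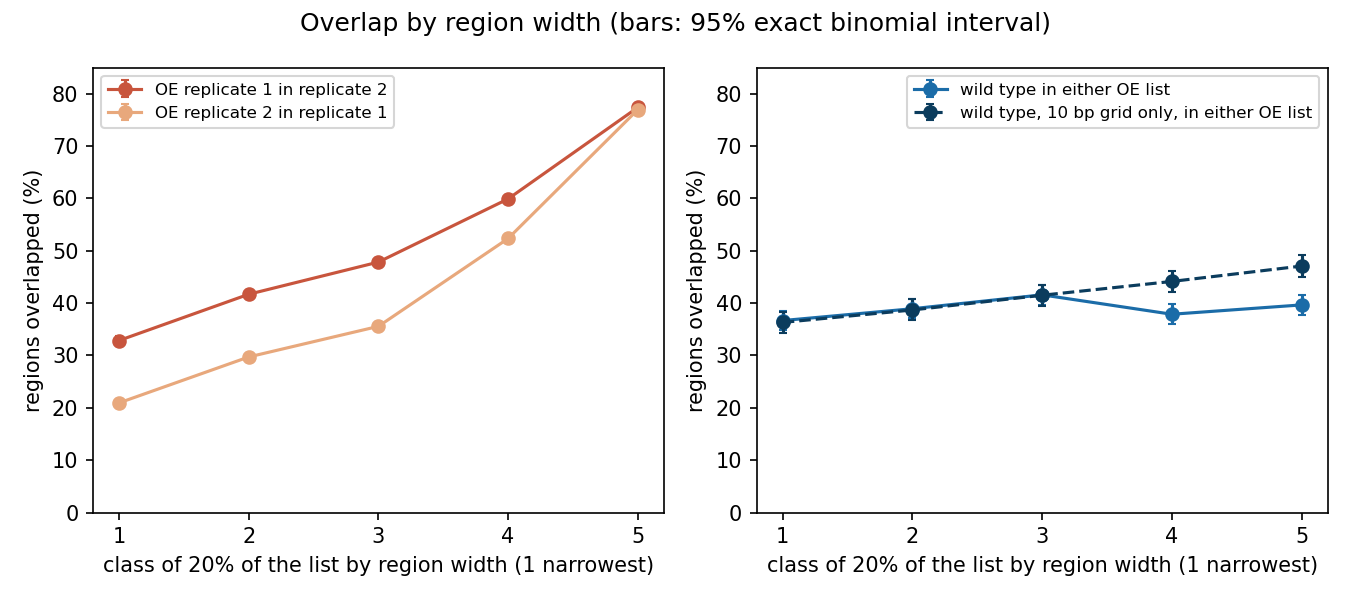
Percentage of regions overlapped by another list (vertical axis) in successive classes of 20% of a list ordered by region width (horizontal axis, 1 narrowest), for the overexpression replicates (left) and the wild-type list (right). Bars are 95% exact binomial intervals. Overlap between the overexpression (OE) replicates rises from 32.9% or 20.9% to about 77%, that of all wild-type regions lies between 36.7% and 41.6%, and that of on-grid wild-type regions, defined by edges on a 10 bp grid, rises from 36.3% to 47.1%.

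The density of regions was also compared in windows of 1 Mb. Across 2463 autosomal windows of that size the numbers of regions in replicates 1 and 2 had a Spearman correlation of 0.93 (Pearson 0.91). Wild type had Spearman correlations of 0.64 with each replicate (Pearson 0.61 with replicate 1 and 0.59 with replicate 2). Its windows held a median of 5 regions, against 26 in replicate 1 and 27 in replicate 2. Counting error in so few regions lowers a correlation, so 0.64 against 0.93 does not by itself show a difference between genotypes. The correlations are across windows of the genome, which are not independent replicates. Among the windows with the most regions, the interval from 17000001 to 18000000 on chromosome 6 held 129 regions in replicate 1, 95 in replicate 2 and 11 in wild type. The interval from 21000001 to 22000000 on chromosome 14 held 104, 94 and 18. The interval from 80000001 to 81000000 on chromosome 12 held 104 and 97 regions in the overexpressing cells and 1 in wild type. Of the 100 densest windows in each list, 59 were common to both overexpression replicates, where 4.06 would be common by chance, and wild type had 33 in common with replicate 1 and 24 with replicate 2. The small wild-type counts limit this comparison as well. Regions also lay close together. Gaps under 2 kb made up 33.5% of the gaps between neighbouring regions in replicate 1 and 18.9% in replicate 2, against 6.83% and 6.87% in 1 random placement of each list. In wild type such gaps made up 5.91%, against 1.65% in a random placement, so close spacing was not particular to the overexpressing cells.

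The next comparison asked whether regions bound in wild-type cells were bound in the overexpressing cells too. Of the 13278 wild-type regions, 3088 (23.3%, interval 22.5 to 24.0%) overlapped a region in both overexpression replicates and 5171 (38.9%, interval 38.1 to 39.8%) in at least 1 of them. With an overlap of at least 50% of both regions these shares were 8.98% and 25.4%, and with the overexpression lists reduced to their 13278 widest regions, a setting added after seeing the data, 7.90% and 21.3%. The remaining 8107 wild-type regions (61.1%) overlapped neither list, although the overexpressing cells had 5.40 times as many regions. By chance, 1.08% of wild-type regions would lie in both lists and 3.55% in at least 1 (permutation p = 0.001 for each, one-sided, 1000 placements, the smallest they can give). Moving every wild-type region by 10 to 100 kb, which keeps the local density of regions, gave 4.80 to 6.00% in at least 1 list. Taken singly, replicate 1 overlapped 4294 wild-type regions (32.3%) and replicate 2 overlapped 3965 (29.9%).

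**Figure D2:**
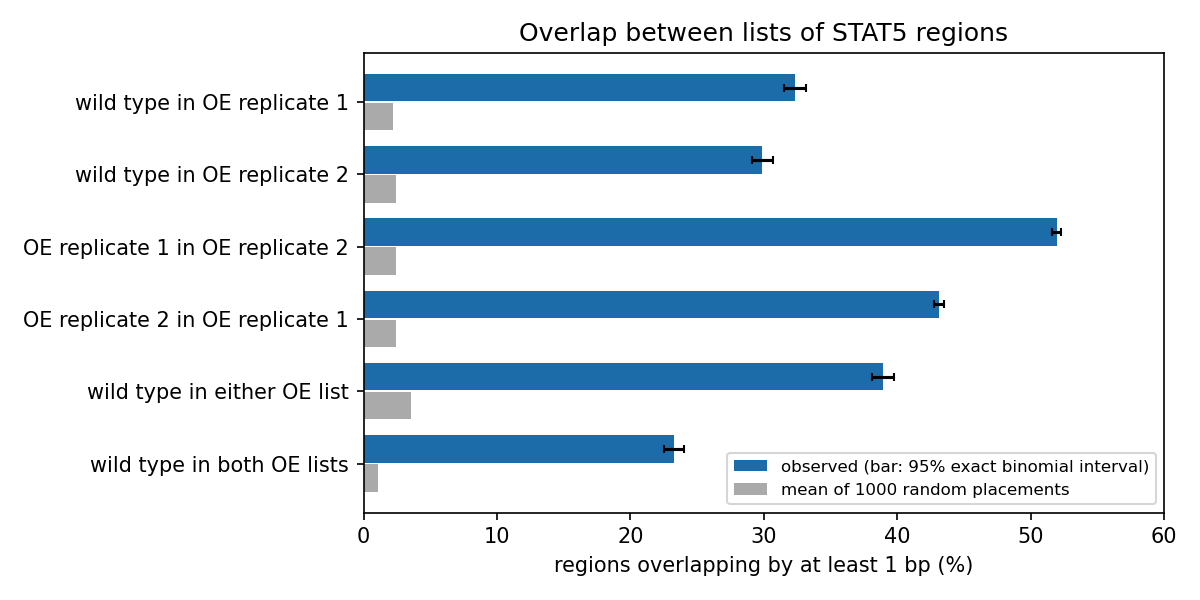
Percentage of the regions of 1 list that overlap another by at least 1 bp (horizontal axis), for each pair of lists named on the vertical axis; OE stands for the STAT5A-overexpressing cells. Blue bars are the observed shares with 95% exact binomial intervals and grey bars the mean of 1000 random placements. The observed shares lie between 23.3% and 51.9%, and the random ones between 1.08% and 3.55%.

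Seen from the overexpressing cells, overlap with wild type was more frequent among regions found in both replicates. Of the replicate 1 regions that replicate 2 also held, 8.93% (interval 8.64 to 9.22%) overlapped a wild-type region, against 3.99% (interval 3.78 to 4.20%) of those in replicate 1 alone. For replicate 2 the shares were 9.49% (interval 9.16 to 9.82%) and 2.05% (interval 1.91 to 2.19%). Overexpression regions that overlapped a wild-type region were wider, with a median of 499 bp against 389 bp in replicate 1 and 569 bp against 372 bp in replicate 2 (p = 1e-05 for each, two-sided permutation test over regions, the smallest it can give). When all lists were merged into 113354 distinct regions, 2984 were in all 3 lists and 27342 in both overexpression replicates but not in wild type. Of the 30326 merged regions in both replicates, 9.84% (interval 9.51 to 10.2%) were thus also in wild type. A further 33024 merged regions were in replicate 1 alone, 40016 in replicate 2 alone and 8107 in wild type alone.

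Among wild-type regions, width separated shared from unshared ones much less. The median was 388 bp for the 5171 wild-type regions overlapped in the overexpressing cells and 378 bp for the 8107 others, a difference that did not pass the test (p = 0.62, two-sided permutation test over regions). Most wild-type widths lie in steps of about 10 bp, so the test can hardly resolve a difference of that size. It does not show that the widths are equal. The wild-type list is made of parts that differ. The edges of 11565 regions (87.1%) lie on a 10 bp grid, with a tolerance of 1 bp at the end, as do those of all replicate 1 regions, and the edges of the other 1713 do not. The off-grid regions had a median width of 511 bp, against 358 bp on the grid, and 21.4% of them (interval 19.4 to 23.4%) overlapped an overexpression list, against 41.5% (interval 40.6 to 42.5%) of the on-grid regions. Among the on-grid regions alone, chosen after the lists were seen, shared regions were wider by 20 bp (medians 368 and 348 bp, p = 2e-05, two-sided permutation test over regions).

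Where wild-type regions overlapped a replicate 1 region, their summits, as the authors' lists give them, lay close to a replicate 1 summit. The median distance to the nearest replicate 1 summit over 4294 wild-type regions was 75 bp, and 63.1% of their summits lay within 100 bp of one. The nearest summit was not required to belong to the overlapping region. The centres of the same wild-type regions lay at a median of 79 bp from a replicate 1 summit. With each summit moved to the relative position of the summit in another region of the set, the median was 88.9 bp, and none of 200 such permutations came as close as the observed summits (permutation p = 0.005, one-sided, the smallest they can give, over regions). The median was 70 bp for the 3088 regions also found in replicate 2 and 85 bp for the 1206 that were not. With summits moved in the same way within each set, the medians were 86.3 and 95.9 bp, so the sets differed there as well. The centres of these regions lay at medians of 76.25 and 86 bp. In the 1206 regions the summits were thus hardly closer than the centres. All these regions were chosen for their overlap with replicate 1, which by itself keeps such distances short.

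Individual regions were chosen by width, since no list gives a score. The widest wild-type region, at 88193503 to 88194510 on chromosome 10, was 1008 bp wide, and the next, at 81359363 to 81360360 on chromosome 12, was 998 bp wide, and both were overlapped in both overexpression replicates. Of the 10 widest wild-type regions, 9 were overlapped in replicate 1 and 7 in replicate 2. The 10 widest regions of each overexpression replicate were all overlapped in the other replicate, and wild type overlapped 4 of those of replicate 1 and 8 of those of replicate 2. The widest region of replicate 2, at 24314354 to 24317394 on chromosome 10, was 3041 bp wide and present in all lists. Among sites with 1 region per list in all 3 lists, the broadest by its narrowest member was at 80762930 to 80763920 on chromosome 7, with widths of 749 bp in wild type, 898 bp in replicate 1 and 768 bp in replicate 2. By the same measure, the broadest site with 1 region in each overexpression replicate and none in wild type was at 121770545 to 121772209 on chromosome 14, with widths of 1529 and 1665 bp. It was followed by a site at 93891463 to 93892863 on chromosome 2, with widths of 1378 and 1269 bp. All positions are on mm9 and counted from 1. Which genes these regions lie in or near was not analysed here, because the gene annotation at hand is of another genome build.

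Regions were spread over all autosomes, with the highest density on chromosome 10 in each of the 3 lists. Wild-type cells had 12.9 regions per Mb on chromosome 10, where the other 18 autosomes ranged from 3.17 on chromosome 4 to 5.74 on chromosome 13. Overexpression replicate 1 had 43.2 per Mb on chromosome 10, against 21.3 to 34.0 on the other autosomes, and replicate 2 had 38.7, against 23.9 to 33.5. Over 5 Mb windows, chromosome 10 held 2.64 times as many regions as the other autosomes in wild type (95% bootstrap interval over windows 2.36 to 2.93). The ratio was 1.59 (1.35 to 1.84) in replicate 1 and 1.39 (1.17 to 1.65) in replicate 2. Chromosome 10 was singled out because it ranked highest, and the intervals do not allow for that choice among 19 autosomes. Chromosome X had 0.901 regions per Mb in wild type, 9.87 in replicate 1 and 9.59 in replicate 2, which is 0.183, 0.355 and 0.346 times the median of the autosomes other than chromosome 10.

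**Figure D3:**
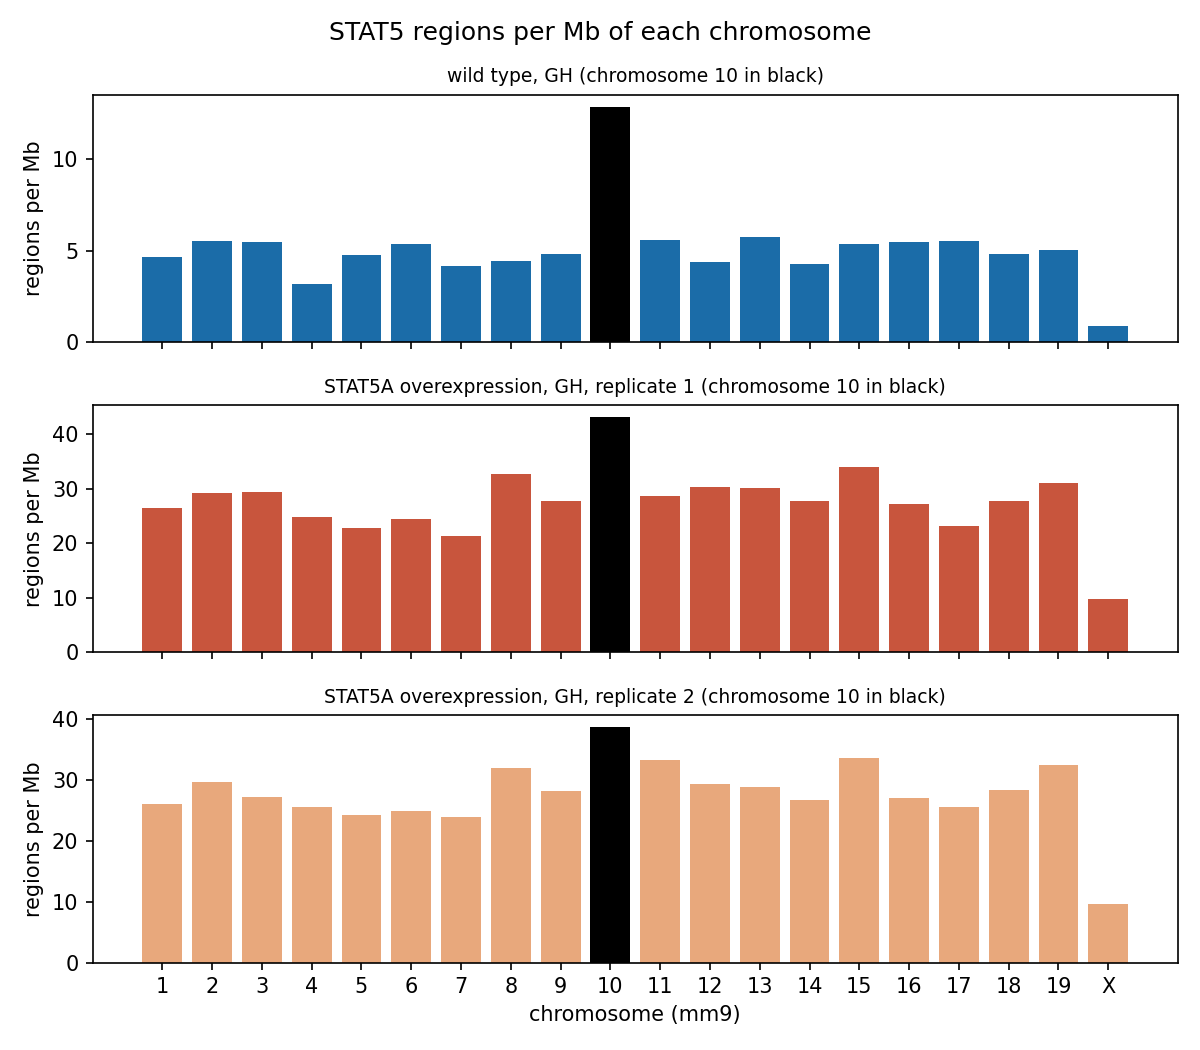
Regions per Mb (vertical axis) on each chromosome of mm9 (horizontal axis) in wild-type cells and in the overexpression replicates, all after growth hormone (GH); each panel has its own scale and there is 1 library per panel. Chromosome 10, in black, stands highest in each panel, at 12.9, 43.2 and 38.7 regions per Mb.

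The excess ran along most of chromosome 10. Of its 25 windows of 5 Mb, 24 held more wild-type regions than the median window of the other autosomes, and 21 did so in replicate 1 and 18 in replicate 2.

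**Figure D4:**
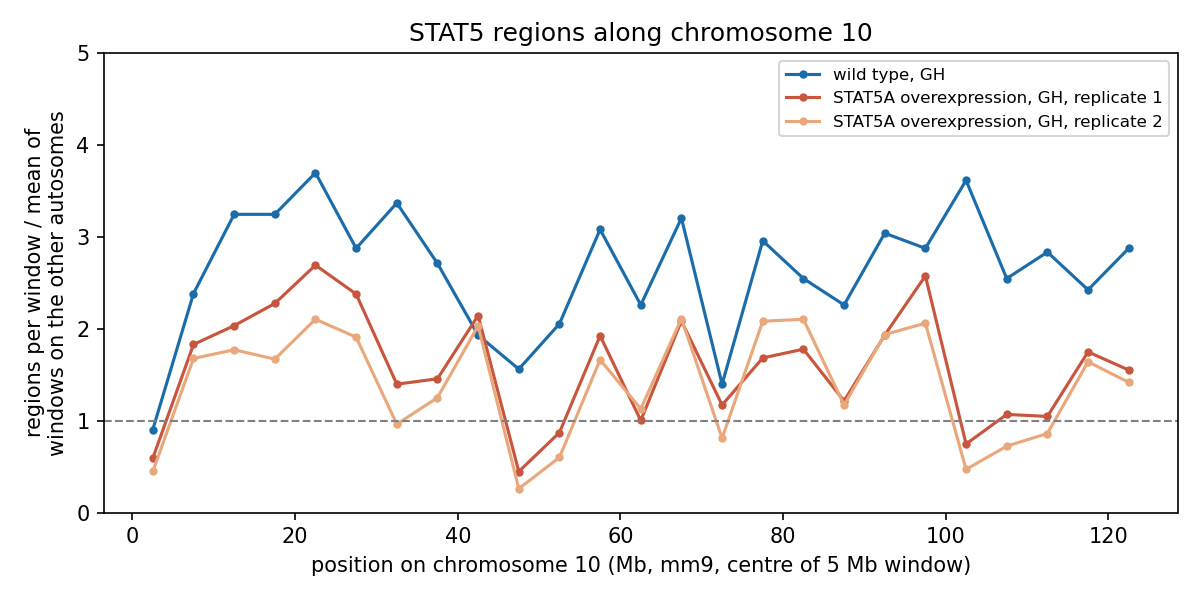
Number of regions in each 5 Mb window of chromosome 10 divided by the mean of the windows on the other autosomes (vertical axis) against position on mm9 (horizontal axis), 1 line per library; the dashed line marks a ratio of 1. The mean over the windows is 2.64 in wild type, 1.59 in overexpression replicate 1 and 1.39 in replicate 2.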

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

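Of 36 alternative values, 11 left the result as reported, 24 moved it and 1 made a difference pass a test that it had not passed. The 11 were 5 shares or ratios within their interval or range, 3 numbers of regions and 3 width differences. The numbers of regions stayed within 1.5 times and the width differences on the same side of the test. Those numbers came from keeping autosomes and chromosome X, which removed few regions or none. None of the values reversed a direction that had passed a test, but shares and numbers of regions have no such direction. Chosen after seeing the data were wider regions, equal list lengths, the 10 bp grid and the omission of chromosome 10. So were shifts of 10 to 100 kb, 10 Mb windows, the reciprocal rule for widths and the chromosome 10 ratio itself. The share of wild-type regions in at least 1 overexpression list, 38.9%, was 25.4% with a reciprocal overlap of at least 50%, 33.5% with centres within 200 bp, 32.3% for the wider part of every list, 21.3% with the overexpression lists reduced to their 13278 widest regions and 41.5% for on-grid wild-type regions. Leaving out replicate 1 or replicate 2 gave 29.9% to 32.3%, and leaving out chromosome 10 gave 39.6%. The share in both lists, 23.3%, was 8.98%, 15.3%, 17.1%, 7.90% and 25.1% under the same first 5 settings. The share of replicate 1 regions in replicate 2, 51.9%, was 32.7% with reciprocal overlap, 39.1% by centres, 49.0% for the wider part and 40.8% among the 13278 widest regions of each list. For replicate 2 regions in replicate 1, 43.1% became 32.6%, 37.7%, 46.3% and 39.7%. At that equal length wild-type regions overlapped replicate 1 in 14.1% and replicate 2 in 15.1%. The wild-type regions were the whole list and not its widest part, so these shares are not matched for width with those between replicates. The chance level of 3.55% was 3.55% when regions of a chromosome were shifted together and 5.41% when regions moved by 10 to 100 kb. Keeping the wider part left 6650, 36437 and 36042 regions by construction. The width difference between shared and other wild-type regions, 10 bp, became 20 bp and passed the test on the grid alone (p = 2e-05, permutation test), and was -10 to 10 bp without either replicate, where it did not pass. The width difference in replicate 1, 110 bp, was 161 bp with reciprocal overlap. The chromosome 10 ratio of 2.64 was 2.74 on the grid and 2.63 with 10 Mb windows. Why the shares moved was not tested, except that the reciprocal rule and a shorter list to match against can only lower a share. Alternatives that need a score, gene positions or the mm9 sequence were not run. No paired analysis was possible because the compared groups, stimulated wild-type and overexpressing cells, share only 1 replicate number, and lists of the unstimulated overexpressing cells were not analysed here. Depth is unknown for every library, and it limits any reading of the numbers of regions.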

Other observations

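The tests below were chosen after the overlaps were seen, except that the distances to regions of another list had not been seen when their tests were set. The quotient of wild-type over overexpression density, each chromosome against the autosomes other than chromosome 10, was lowest on chromosomes 4 (0.695), 8 (0.771) and 12 (0.814) and, after chromosome 10, highest on chromosomes 17 (1.30) and 6 (1.25). Against replicates 1 and 2 singly it was 0.699 and 0.692 on chromosome 4 and 1.36 and 1.25 on chromosome 17. With 1 wild-type library, these differences between genotypes were not tested. Of the 100 densest 1 Mb windows of the wild-type list, 57 lay on chromosome 10, against 20 for replicate 1 and 17 for replicate 2. The densest, from 57000001 to 58000000, held 30 regions in wild type, 29 in replicate 1 and 28 in replicate 2, so that it was as dense in wild type as in cells with many more regions. Within wild type the chromosome 10 ratio was 2.84 (2.50 to 3.19) for regions in neither overexpression list and 2.29 (1.84 to 2.81) for regions in both.

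The wild-type list had a larger excess of regions on chromosome 10 than the overexpression lists. Its ratio of chromosome 10 to the other autosomes was 1.77 times that of the overexpression lists added together (95% bootstrap interval over windows 1.56 to 2.08), 1.66 times that of replicate 1 (1.47 to 1.92) and 1.89 times that of replicate 2 (1.65 to 2.24), while the overexpression replicates differed from each other by 1.14 (1.07 to 1.22). On the other autosomes the quotient of replicate 1 over replicate 2 ran from 0.867 on chromosome 11 to 1.10 on chromosome 3. A difference between replicates of about that size was thus not particular to chromosome 10. The bootstrap intervals cover windows and not cultures, so with 1 wild-type library a difference between genotypes was not tested. A local cluster is argued against as the whole excess, since 96% of the chromosome's windows (24 of 25) held more wild-type regions than the median window of the other autosomes. That count describes the list, since it was known before its test was set. The off-grid regions are argued against as the source (on-grid ratio 2.74, interval 2.45 to 3.05). A site density that all 3 lists share alike cannot be excluded. The quotient of 1.77 lay above those of the other autosomes (0.695 to 1.30), but lists of unlike length and calling need not give 1. Extra copies of the whole chromosome in the cultured wild-type cells stay open: the 96% had been seen before and is no separate evidence for them, and the ratios of 1.59 and 1.39 in the overexpression lists would need another source or extra copies there too. Copy number was not measured, and a difference between the cell lines in binding or chromatin was not tested.

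The wild-type list appears to join regions of different origin. On-grid regions have summits at multiples of 5 in 99.8% of cases, and off-grid regions in 20.6%, near the share of any whole number. The off-grid regions vary less in width (SD 49.8 bp against 121 bp), and 10.0% of them lie on chromosome 10, against 13.0% of on-grid regions. On-grid regions overlapped an overexpression list with odds 2.62 times those of off-grid regions (Fisher's exact test over regions, two-sided, p = 1.4e-61).

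Most wild-type regions, 61.1%, overlapped neither overexpression list. Most stayed unshared without the off-grid regions or without chromosome 10: 41.5% of on-grid regions and 39.6% of regions outside chromosome 10 were overlapped, against 38.9% of all. The 5171 overlapped regions are fewer than 50% of either set, so neither share could have reached 50%. These values describe the list and are no separate test of either explanation. Calls placed evenly along each chromosome are argued against as the whole cause. Of the unshared wild-type regions, 51.5% lay within 10 kb of an overexpression region, where 1000 random placements had a mean of 39.6% and a highest value of 41.3%. Most of that nearness is thus reached by even placement, and how many of these regions are such calls was not tested. The placements did not exclude gaps or unmappable sequence, and calls that follow open chromatin or mappable sequence without STAT5 could give such nearness too, which was not tested. Binding by STAT5B, which the overexpressing cells lack, differences between cell lines and the unknown depths stay open as untested explanations.

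Many regions of each overexpression list were absent from the other, 34396 of replicate 1 and 40852 of replicate 2. Weak regions near the calling thresholds are a candidate explanation, with width standing in for strength, which the lists do not give. The widest 20% of regions overlapped 2.35 times as often as the narrowest 20% in replicate 1 and 3.67 times as often in replicate 2, and had a centre within 200 bp, a measure whose chance level was about the same in each width class, 3.44 and 3.08 times as often. Displaced calls of the same sites are argued against as the main cause, since 18.9% of the unshared regions of both lists lay within 1 kb of a region of the other list. The share was 24.0% for replicate 1 and 14.6% for replicate 2. How the lists were called and a possibly different control library of replicate 2 also remain open.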
